A study of Arabidopsis thaliana with 4 samples.

How the data were processed

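The series holds 4 RNA sequencing libraries from leaves of 2-week-old *Arabidopsis thaliana* plants grown on soil in long days. Per the labels, they come from Col-0 and sme1-1 plants kept at 20 °C, and from Col-0 and sme1-1 plants exposed to 4 °C for 24 h, with 1 library per group. Per the labels, the light was 90 µmol m-2 s-1 during growth and 40 µmol m-2 s-1 during the exposure to cold, so light and temperature differ together.

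Each library has a table with 1 line per gene. The deposited count is the number of uniquely mapped reads per gene, per the file headers. The deposited coverage is the percent of the gene length covered by reads. The deposited RPKM (reads per kilobase and per M reads) was recomputed from the count, the gene length and the library total, and every value was within 1e-6 of it. The authors name TAIR10 as the genome build in their processing notes. The aligner, the counting program and the rule by which a read was taken as unique are not given in the sources used here. Counts of uniquely mapped reads leave out reads that fit several gene copies equally well. This is a limit for near-identical genes such as SME1 and SME2, KIN1 and its neighbour COR6.6, or the RBCS genes. The strand of a read is not in the tables, so antisense transcription cannot be told from sense. Tables list genes with at least 1 read: 21507, 21401, 21551 and 21352 genes in the libraries labelled Col-0 20 °C, sme1-1 20 °C, Col-0 4 °C and sme1-1 4 °C. A gene missing from a table was taken as a count of 0. In all, 23049 genes were in at least 1 table and 20042 in all 4. The gene length differed between tables for 36 genes, and lengths were not used in the comparisons.

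Gene symbols and products came from the TAIR10.1 annotation by gene code, with 22861 of the 23049 codes matched and 188 not. No coordinate of that annotation is printed. It served to find genes within 2 Mb of SME1 for 1 test in the closing section. That SME1 is AT2G18740 and SME2 is AT4G30330 is background knowledge.

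Counts were scaled with TMM factors (edgeR 4.0.16: 0.988, 1.014, 0.964 and 1.036 in the order above). Genes with a mean of at least 1 CPM over the 4 libraries were kept, 17218 genes. Log2 ratios between 2 libraries used a prior count of 2, so they are drawn towards 0 at low counts. Folds and CPM carry no prior count. Intervals are exact 95% intervals for the ratio of 2 counts. A gene with 0 counts in 1 library is given as at least so many fold apart, from an upper limit of 3 counts. At depths of 44.6 M to 47.2 M reads this limit is 0.0619 to 0.0681 CPM after TMM scaling.

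Each comparison involved single libraries: sme1-1 against Col-0 at each temperature, 4 °C against 20 °C in each genotype, and the difference between the temperature ratios. Within them, genes at least 2-fold apart were counted and no p was computed. Both comparisons of genotype share no library with each other, nor do both comparisons of temperature, and overlaps are set against the number expected for independent lists. An additive model of genotype and temperature with 1 residual degree of freedom was fitted over the 4 libraries with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over all genes (threshold 0.05; common dispersion 0.021, prior degrees of freedom 11.5), and with DESeq2 1.42.0 as an alternative. A count "adjusted over the list alone" repeats the adjustment over the members of 1 list. Further tools were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

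The comparisons, the gene lists, the thresholds and the alternatives in the closing section were fixed before the data were examined, unless the text says otherwise. The rule for named genes was SME1 and SME2, the 10 largest log2 ratios in each direction among genes passing the filter (for the additive model, among those past the threshold), and for each list the 2 to 4 measured members furthest from 0. List members named beside a count of 5 or fewer calls, and AGL24, CYP71A13 and MYB111 where outside that rule, were chosen after their values were seen. The lists cover LSM proteins (the Sm genes were left out), splicing regulators, cold-regulated genes, cold signalling, heat shock proteins, flavonoids, photosynthesis, the circadian clock, flowering time, osmoprotectants and sugars, abscisic acid, salicylic acid and defence, jasmonate, antioxidant enzymes, membrane lipids, the cell cycle, markers of other cell types and organs, cytosolic ribosomal proteins, and plastid-encoded and mitochondrion-encoded genes. The cytosolic ribosomal, plastid-encoded and mitochondrion-encoded lists were included as signs of how RNA was selected for the libraries. Differences in them may come from library preparation, which was not tested. The hand-written lists hold 252 members. SME1, SME2 and the members whose gene code and symbol the annotation pairs were used, 234 in all, and 18 were left out, among them all 11 Sm genes. Each list median with at least 3 measured members was placed among 10000 random lists of the same size, matched on expression in 20 bins (seed 1). Random lists do not carry the correlation between members of a pathway, so a percentile is a description and not a p.

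The procedure was tested on simulated data with 4 libraries, the fitted dispersion and 200 altered genes. The genotype term recovered 83% of 2-fold and 97% of 4-fold changes, with 6 false calls of 186, and the temperature term 80% and 98%, with 10 false calls of 188. Each simulation altered 1 factor only, held no interaction and gave all 17218 genes the same dispersion. In the real libraries the genotype term called 7024 genes, so the simulated false calls do not give the rate there. Of 100 simulated lists of 12 unaltered genes, 5 fell outside the middle 95%, and of 100 shifted by 1 on the log2 scale, 92 lay above percentile 97.5.

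Alternatives were DESeq2's size factors and library totals in place of TMM, no filter and a mean of at least 5 CPM, prior counts of 0.5 and 5, at least 3-fold in place of 2-fold, an adjusted p of 0.1, and DESeq2 in place of edgeR. The use of every list member by its gene code, the Sm genes by gene code as a list of their own, the mitochondrial dysfunction list without OM66, and the comparison of the library labelled sme1-1 4 °C with that labelled Col-0 20 °C were added after the data were seen.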

Results

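Leaf transcriptomes of 2-week-old *Arabidopsis thaliana* plants were measured by RNA sequencing in 4 libraries. The labels give the wild-type accession Col-0 and the mutant line sme1-1, each kept at 20 °C or exposed to 4 °C for 24 h. SmE1 is a protein of the Sm ring, the protein ring around the spliceosomal small nuclear RNAs. Each combination of genotype and temperature was represented by 1 library, so no difference between 2 libraries could be set against a spread between replicates. The libraries held 44.6 M (labelled Col-0 20 °C), 45.0 M (sme1-1 20 °C), 47.2 M (Col-0 4 °C) and 46.8 M (sme1-1 4 °C) uniquely mapped reads in genes. A count of 0 allowed a level of up to 0.0681, 0.0658, 0.0660 and 0.0619 CPM (TMM-scaled counts per M reads) in these libraries, in the same order. After the filter on low counts, 17218 genes were compared. All intervals below are 95% intervals for counting error between 2 libraries and hold no biological spread.

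The targeted gene was examined first because it checks the labels. SME1 (AT2G18740, on chromosome 2) was read at 14.9 CPM (655 reads) in the library labelled Col-0 20 °C and at 27.5 CPM (1252 reads) in the library labelled sme1-1 20 °C. It was read at 0.704 CPM (32 reads) in the library labelled Col-0 4 °C and at 0.887 CPM (43 reads) in the library labelled sme1-1 4 °C. SME1 was thus not lower in either library labelled sme1-1 than in its Col-0 counterpart: it was 1.85-fold higher at 20 °C (1.68 to 2.03) and 1.26-fold higher at 4 °C (0.779 to 2.06). It was 21.1-fold lower (14.8 to 31.1) in the library labelled Col-0 4 °C than in that labelled Col-0 20 °C, and 31.0-fold lower (22.8 to 43.0) in the library labelled sme1-1 4 °C than in that labelled sme1-1 20 °C. Reads covered 96.0% and 98.4% of the gene length in the 2 libraries labelled 20 °C, and 56.5% and 53.0% in the 2 labelled 4 °C. The paralogue SME2 (AT4G30330) lay between 9.26 and 11.4 CPM in all 4 libraries. The targeted gene therefore went against the labels, and the libraries are named below by what they were labelled as; every direction between genotypes or temperatures is a direction between labels.

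**Figure D1:**
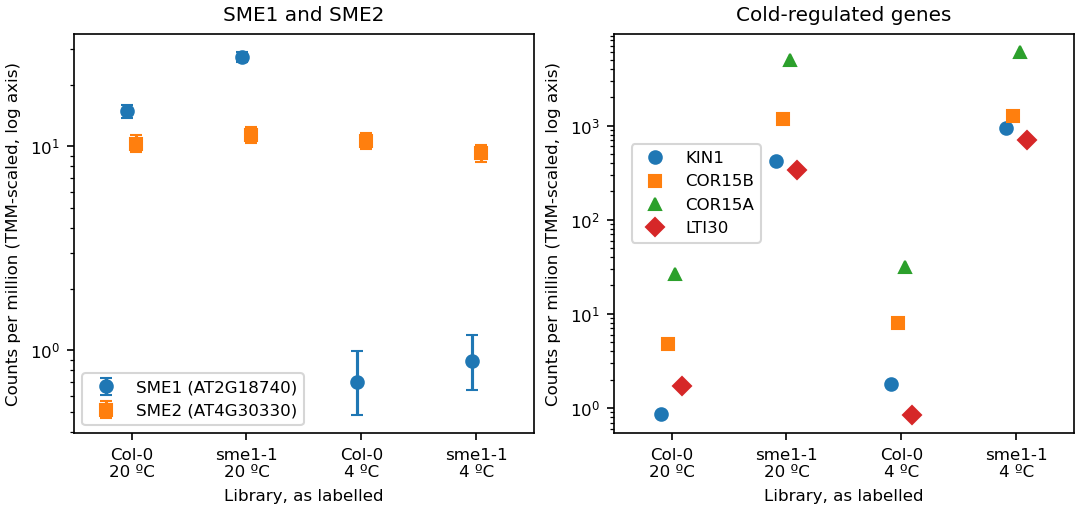
TMM-scaled CPM (log axis) in the 4 libraries, 1 point per library and gene; left, SME1 and SME2 with 95% Poisson intervals for counting error; right, the 4 cold-regulated genes with the largest ratio between the libraries labelled 20 °C. SME1 lies at 14.9 and 27.5 in the libraries labelled 20 °C and at 0.704 and 0.887 in those labelled 4 °C, while KIN1 lies at 422 and 940 in the libraries labelled sme1-1 and at 0.862 and 1.78 in those labelled Col-0.

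The whole transcriptomes were most alike between libraries that carried the same genotype label. Across the 17218 genes, which are not independent replicates, Pearson's r of log2 CPM was 0.990 between the 2 libraries labelled Col-0 and 0.974 between the 2 labelled sme1-1. It was 0.935 between the 2 labelled 20 °C and 0.919 between the 2 labelled 4 °C. The 10 most abundant genes held 12.3% and 12.8% of the counts in the libraries labelled Col-0, and 10.9% and 10.7% in those labelled sme1-1.

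The libraries labelled sme1-1 20 °C and Col-0 20 °C differ by their genotype label. Cold-regulated genes were the most distant group: 17 of 19 measured members were at least 2-fold higher in the library labelled sme1-1 20 °C and none was at least 2-fold lower. KIN1 was 489-fold higher (356 to 692), from 0.862 to 422 CPM. COR15A and COR15B, whose products protect chloroplast membranes during freezing, were 192-fold (181 to 203) and 245-fold (214 to 282) higher, and the dehydrin LTI30 was 194-fold higher (155 to 246). The list's median log2 ratio was 4.15, above all or nearly all of 10000 random lists of the same size matched on expression (percentile 100, middle 95% from -0.35 to 0.40). The galactinol synthase GOLS3 was 183-fold higher (138 to 248) and AZI1, a gene of systemic defence priming, 185-fold higher (163 to 212). AT4G01985, the flavonol glycosyltransferase gene UGT78D3, AT3G62550 and BT2 completed the 10 largest differences in this direction, with log2 ratios of 6.87, 6.26, 6.23 and 6.19.

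Flavonoid and anthocyanin genes were also higher in the library labelled sme1-1 20 °C. Of 14 measured members 8 were at least 2-fold higher and none at least 2-fold lower, with a median log2 ratio of 1.49 (percentile 100). Chalcone synthase (CHS), which catalyses the first committed step, went from 661 to 2680 CPM, a 4.06-fold difference (4.00 to 4.11). The glutathione S-transferase gene TT19 was 5.39-fold higher (4.94 to 5.89). Osmoprotectant and sugar genes had a median of 0.78 (percentile 99.8), with 3 of 9 at least 2-fold higher and 1 lower. Sucrose synthase SUS1 was 18.6-fold higher (17.1 to 20.3) and the chloroplast amylase AMY3 6.13-fold higher (5.57 to 6.75), while GOLS2 was 3.02-fold lower (2.39 to 3.84). Cytosolic ribosomal protein genes had a median of 0.46 (percentile 98.6), with 12 of 14 members above 0 and 1 at least 2-fold lower. This list holds only the 18 genes whose product description opens with the name of a ribosomal subunit. Ribosomal protein genes described otherwise are not on it, so it does not stand for the whole class.

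The largest differences in the other direction at 20 °C were in PAP17, an acid phosphatase gene of phosphate starvation, which was 43.2-fold lower (32.6 to 58.4) in the library labelled sme1-1, and in AT2G04050, a MATE efflux gene read at 3.20 CPM against 0.0439 CPM (72.9-fold lower, 19.8 to 608, from 2 reads in the lower library). SRG3 was 32.9-fold lower (24.3 to 45.4), the prenyltransferase gene cPT4 21.6-fold (18.5 to 25.3) and EXPA8, an expansin that loosens cell walls, 19.2-fold (16.3 to 22.8). AT1G52100, JAL33, AT3G23510, FTM1 and AT2G27420 had log2 ratios of -4.87, -4.07, -3.92, -3.86 and -3.79. Heat shock genes had a median of -0.78 (percentile 1.1), with HSFA2 6.83-fold (3.95 to 12.7) and HSP101 2.89-fold (2.56 to 3.27) lower. Photosynthesis genes had a median of -0.39 (percentile 1.7). Within that list the Rubisco genes RBCS2B and RBCS3B and Rubisco activase (RCA) were 2.97-, 2.61- and 2.90-fold lower, and the other 18 of 21 were within 2-fold. Plastid-encoded genes had a median of -0.31 (percentile 0.1).

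Further lists fixed before the data were examined had medians inside the middle 95% of their random lists at 20 °C. Circadian clock genes went both ways, with 6 of 13 at least 2-fold higher and 4 lower: PRR5 was 42.5-fold higher (29.9 to 62.3), FKF1 42.0-fold (11.3 to 353) and TOC1 5.14-fold (4.62 to 5.74). The cold-signalling list (median 0.39, percentile 95.8) held CBF2, which was 5.49-fold higher (3.73 to 8.32), RAP2.1, which was 6.39-fold higher (5.63 to 7.27), and ZAT10, which was 3.26-fold lower (2.93 to 3.64). Among splicing regulators (median 0.33, percentile 96.4), RS40 was 3.67-fold (3.47 to 3.90) and PRMT5, an arginine methyltransferase of Sm proteins, 2.67-fold (2.45 to 2.91) higher, and SCL33 was 2.81-fold lower (2.5 to 3.15). None of the 11 measured LSM genes, relatives of the Sm genes, differed by 2-fold (median 0.35, percentile 94.4). The 11 Sm genes of that list were left out of it because the annotation does not pair their codes with these symbols; taken by gene code alone, a choice made after seeing the data, they had a median of 0.61 (percentile 99.6), with none 2-fold apart. Medians were 0.34 for abscisic acid response, 0.12 for salicylic acid and defence, 0.52 for jasmonate response, 0.18 for flowering time, -0.14 for antioxidant enzymes, -0.33 for membrane lipid genes, 0.02 for the cell cycle and -0.34 for mitochondrion-encoded genes. PR5 was 19.7-fold higher (17.9 to 21.6) and CBP60G 6.37-fold lower (4.81 to 8.56) within the defence list, and MYC2 was 4.93-fold lower (4.41 to 5.52) within the jasmonate list. Over all genes, 1442 were at least 2-fold higher and 1309 at least 2-fold lower in the library labelled sme1-1 20 °C, 16.0% of the genes compared. The balance depended on scaling and filter, with 1539 and 1210 genes under library totals and 2459 and 2649 without a filter.

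At 4 °C the library labelled sme1-1 was again far above that labelled Col-0 in cold-regulated genes, with 16 of 19 at least 2-fold higher, none at least 2-fold lower and a median log2 ratio of 4.41 (percentile 100). LTI30 was 837-fold higher (610 to 1180), KIN1 528-fold (424 to 665), GOLS3 250-fold (192 to 331), COR15A 194-fold (184 to 204) and RD29A 101-fold (96.0 to 106). COR15B, AZI1, PXMT1, AT3G62550 and AT1G16850 completed the 10 largest, with log2 ratios of 7.28, 7.27, 7.18, 6.71 and 6.50. The regulators CBF2 and RAP2.1 were 6.42-fold (0.572 against 3.67 CPM) and 5.82-fold (interval 5.12 to 6.64) higher and ZAT10 was 4.33-fold lower (3.85 to 4.88), in a list with a median of 0.61 (percentile 99.2), 4 of 11 members at least 2-fold higher and 1 lower. Flavonoid genes had a median of 1.15 (percentile 100), with 8 of 14 at least 2-fold higher, 1 lower and CHS 4.24-fold higher (4.19 to 4.29). Osmoprotectant genes had a median of 1.46 (percentile 100), with 7 of 9 at least 2-fold higher and SUS1 41.6-fold higher (38.4 to 45.2).

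The defence and abscisic acid lists, whose medians lay inside the middle 95% at 20 °C, lay outside it at 4 °C. At 20 °C, 5 of 14 abscisic acid genes were already at least 2-fold higher and 3 lower (percentile 96.0). Of 13 defence genes, 3 were higher and 3 lower there (percentile 73.8). The salicylic acid and defence list had a median of 0.84 (percentile 99.9), with 6 of 13 at least 2-fold higher and 3 lower. PAD3, which makes the phytoalexin camalexin, was 86.4-fold higher (49.2 to 168) in the library labelled sme1-1 4 °C, PR5 47.6-fold (42.4 to 53.5) and SARD1 3.76-fold (3.14 to 4.54). The abscisic acid list had the same median, 0.84 (percentile 100), with 7 of 14 at least 2-fold higher and 2 lower, and in it RD29B was 35.9-fold (25.8 to 51.5) and ABI5 7.40-fold (4.52 to 12.8) higher, while HAI1 was 3.60-fold lower (2.74 to 4.78). The flowering list had a median of 0.72 (percentile 99.3), with SOC1 4.46-fold higher (4.11 to 4.84).

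Heat shock genes were lower in the library labelled sme1-1 4 °C, with a median of -1.68 (percentile 0) and 4 of 6 members at least 2-fold lower; HSFA2 was 9.33-fold lower (5.55 to 16.8) and ROF2 5.35-fold (4.19 to 6.90). Cell cycle genes had a median of -0.66 (percentile 1.7), with CYCD3;1 2.64-fold lower (2.43 to 2.88). Plastid-encoded and mitochondrion-encoded genes had medians of -0.31 (percentile 0.7) and -0.58 (percentile 1.4), with 10 of 64 and 5 of 15 at least 2-fold lower and 2 and 1 higher. Both lists were included as signs of RNA selection, and library preparation could not be told apart from expression in them. FTM1, at 2.86 CPM in the library labelled Col-0 4 °C, had no read in that labelled sme1-1 4 °C and was at least 46.2-fold lower. PAP17 was 32.8-fold lower (25.2 to 43.5), SRG3 28.0-fold (20.6 to 39.1), MIOX2 28.6-fold (14.8 to 63.2) and EXPA8 17.5-fold (14.7 to 21.1). AT1G52100, AT1G15825, AT2G27420, AT3G23510 and AT1G15830 had log2 ratios of -5.62, -4.36, -4.35, -4.35 and -4.05. The 11 Sm genes, by gene code alone, had a median of 0.45 (percentile 96.4), with SmD1a the one at least 2-fold higher. Medians inside the middle 95% were 0.36 for LSM genes, 0.31 for splicing regulators, -0.36 for photosynthesis, 0.34 for the clock, 0.02 for jasmonate response, 0.38 for antioxidant enzymes, -0.35 for membrane lipid genes and 0.41 for cytosolic ribosomal proteins. Within these lists, 6 of 21 photosynthesis genes were at least 2-fold lower and none higher. Of 13 clock genes, 6 were at least 2-fold higher and 3 lower. Over all genes, 1724 were at least 2-fold higher and 1653 at least 2-fold lower in the library labelled sme1-1 4 °C, 19.6% of the genes compared. With library totals in place of TMM the counts were 2009 and 1335 (60.1% higher), and without a filter 2578 and 3108 (45.3% higher).

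The difference between the genotype labels recurred in the second pair of libraries, which shares no library with the first. Of the genes at least 2-fold higher at 20 °C, 1107 were also at least 2-fold higher at 4 °C, against 144 for independent lists. For genes at least 2-fold lower the overlap was 890, against 126. A further 12 genes were at least 2-fold apart in opposite directions. Across genes, Pearson's r of the log2 ratios was 0.84 and Spearman's rho 0.80. In an additive model of genotype and temperature labels (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 3533 genes were higher and 3491 lower with the label sme1-1. With library totals in place of TMM, 4161 were higher and 3071 lower, and with DESeq2 2793 and 2617. This model has 1 residual degree of freedom, and its residual holds noise together with any difference in response between the genotypes. In edgeR its genotype term called 7024 of all 17218 genes. The counts of list members below were not tested against that share, and a list with calls is not thereby singled out. Past the threshold were 18 of 19 cold-regulated genes, all higher, among them KIN1 (log2 8.99 ± 0.23 SE, adjusted p = 4.5e-10 in edgeR), COR15A (7.59 ± 0.22, adjusted p = 6.03e-10) and RD29A (6.21 ± 0.26, adjusted p = 9.87e-09). Adjusted over the list alone the count was also 18. PAP17 (-5.23 ± 0.21) and EXPA8 (-4.20 ± 0.18) were among the genes lower past the threshold. Past it were also 10 flavonoid genes higher and 1 (MYB111) lower of 14, 7 osmoprotectant genes higher and 1 lower of 9, 5 heat shock genes lower of 6, 10 splicing regulators higher and 3 lower of 21, and 9 photosynthesis genes lower and 1 higher of 21. Adjusted over each list alone, these counts were 10 and 2, 7 and 1, 5, 11 and 4, and 9 and 1. In DESeq2 the heat shock genes HSP90.1 and HSP70 and the splicing regulators SR34 and RS31a did not pass, which left 3 heat shock genes lower and 9 splicing regulators higher and 2 lower, while the calls in the other 3 lists and among the cold-regulated genes also passed there. Of the 11 LSM genes 4 were higher (3 adjusted over the list alone, 1 in DESeq2), and of the 11 Sm genes by gene code alone 6 were higher (6 adjusted over the list alone, 5 in DESeq2), SmD1a (1.09), SmBb (0.91), SmD2b (0.62), SmD1b (0.61), SmF (0.61) and SmD2a (0.55). Plastid-encoded genes had 21 of 64 lower (12 adjusted over the list alone, 13 in DESeq2), mitochondrion-encoded genes 5 of 15 lower (5 and 2), and ribosomal protein genes 6 of 14 higher and 1 lower (6 and 1 over the list alone, 4 and 1 in DESeq2). Calls higher and lower were 6 and 3 for the clock, 5 and 1 for cold signalling, 7 and 4 for abscisic acid, 5 and 4 for defence, 2 and 1 for jasmonate, 2 and 2 for antioxidant enzymes, and 1 and 3 for membrane lipids, all of which also passed in DESeq2; adjusted over the list alone they were 6 and 4, 7 and 1, 7 and 4, 5 and 4, 3 and 1, 2 and 2, and 1 and 4. The 3 clock genes lower past the threshold in edgeR were RVE8 (log2 -1.78 ± 0.16 SE), LHY (-1.42 ± 0.16) and PRR9 (-1.35 ± 0.18). PRR5 (5.21 ± 0.22), FKF1 (4.99 ± 0.51) and TOC1 (2.35 ± 0.16) were among the 6 higher. Flowering genes had 3 higher and 1 lower (4 and 1 over the list alone, 2 and 0 in DESeq2) and cell cycle genes 2 lower (1 and 1). SME1 was higher with the label sme1-1 by a log2 fold of 0.71 ± 0.22 (adjusted p = 0.0225 in edgeR), and DESeq2 gave an adjusted p of 0.0739.

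**Figure D2:**
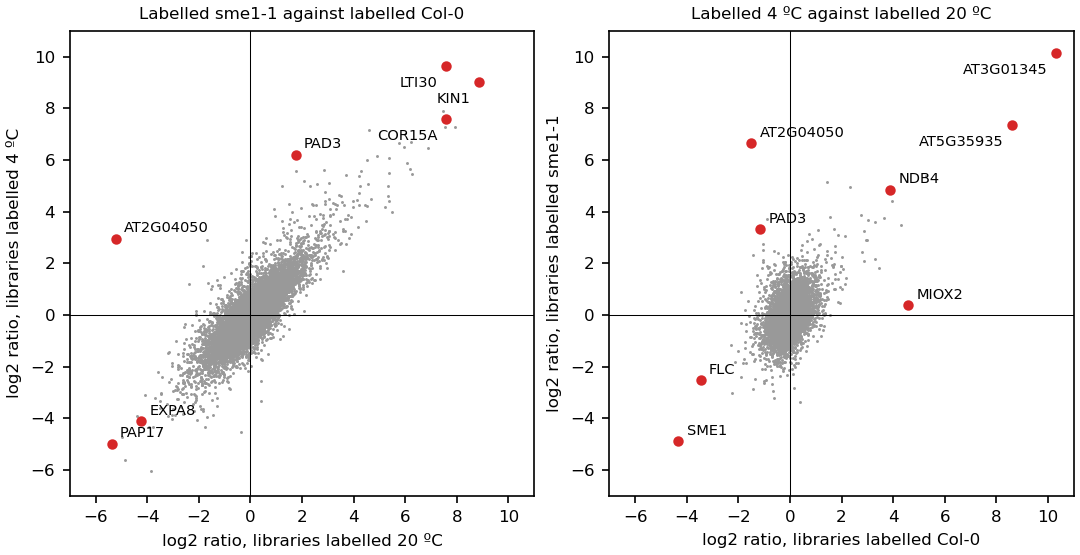
Log2 ratios of the 17218 genes between libraries as labelled, 1 grey point per gene, with some of the named genes in red; left, sme1-1 against Col-0 at 4 °C (vertical) against the same at 20 °C (horizontal); right, 4 °C against 20 °C in sme1-1 (vertical) against the same in Col-0 (horizontal). Pearson's r across genes is 0.84 on the left and 0.45 on the right, where SME1, at -4.32 and -4.89, is the lowest gene on both axes.

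The libraries labelled Col-0 4 °C and Col-0 20 °C differ by their temperature label. Cold-regulated genes differed little: their median log2 ratio was 0.16, 2 of 19 were at least 2-fold higher (COR413IM1, 2.06-fold, 1.72 to 2.47, and KIN1, 2.07-fold, 1.39 to 3.12) and LTI30 was 2.06-fold lower (1.38 to 3.13). That median lay at percentile 99.8 of its random lists, whose middle 95% ran from -0.08 to 0.11. CBF2 was at 0.703 and 0.572 CPM, an interval from 2.16-fold lower to 1.41-fold higher. The largest difference was in AT3G01345, a gene of uncharacterized product, at 0.408 CPM in the library labelled 20 °C and 577 CPM in that labelled 4 °C (1410-fold, 894 to 2380). AT5G35935, with no read in the library labelled Col-0 20 °C, was at least 251-fold higher, and SADHU3-2, of a retroelement family, at least 23.9-fold higher. MIOX2 was 29.2-fold higher (14.6 to 68.4), the alternative NADH dehydrogenase gene NDB4 16.6-fold (9.71 to 30.9) and QQS 13.7-fold (8.62 to 23.2). AT1G43590, AT5G53230, the chromatin remodelling gene chr31 and LBD26 had log2 ratios of 4.30, 3.94, 3.45 and 3.31.

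SME1 was the most reduced gene in the library labelled Col-0 4 °C. FLC, a floral repressor, was next, 12.6-fold lower (7.02 to 25) at 0.264 against 3.34 CPM. AGL24, a promoter of flowering, was 3.59-fold lower (2.98 to 4.34). AT5G03360, AT3G55646, AT5G36920, AT5G11330, CEL2, AT5G46600 and AT1G50040 had log2 ratios between -2.28 and -1.88. Heat shock genes were higher, with all 6 above 0, a median of 0.51 (percentile 99.9) and HSP70 2.01-fold higher (1.87 to 2.16). All 14 flavonoid genes were above 0, with a median of 0.27 (percentile 100). Plastid-encoded genes had the same median, 0.27 (percentile 100), and the clock list 0.24 (percentile 100). Cell cycle genes were at 0.24 (percentile 99.3), jasmonate genes at 0.22 (percentile 98.5) and the 3 guard cell markers at 0.28 (percentile 98.9). The copper/zinc superoxide dismutase genes CSD2 and CSD1 were 2.55-fold (2.48 to 2.63) and 2.32-fold (2.2 to 2.45) lower, in an antioxidant list with a median of 0.10. Medians inside the middle 95% were -0.06 for LSM genes, 0.00 for splicing regulators, 0.01 for cold signalling, 0.10 for photosynthesis, 0.09 for flowering time, 0.14 for osmoprotectants, 0.12 for abscisic acid, -0.12 for defence, 0.03 for membrane lipids, 0.06 for cytosolic ribosomal proteins and -0.14 for mitochondrion-encoded genes. With library totals in place of TMM, the medians of splicing regulators, cold signalling and membrane lipids changed sign, to -0.03, -0.03 and -0.01. Over all genes, 156 were at least 2-fold higher and 121 at least 2-fold lower in the library labelled Col-0 4 °C, 1.6% of the genes compared, and with library totals 137 and 134. The number depended on the filter: without one it was 1127 and 1120, 9.7% of the genes compared, and with a mean of at least 5 CPM 80 in all.

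The libraries labelled sme1-1 4 °C and sme1-1 20 °C also differ by their temperature label. AT3G01345 (1210-fold, 857 to 1770) and AT5G35935 (329-fold, 90.8 to 2720) again led the genes higher in the library labelled 4 °C. AT2G04050 was 201-fold higher (55.3 to 1660), AT2G18193 38.1-fold (25.8 to 58.5) and NDB4 31.0-fold (21.2 to 47.3). SADHU3-2, AT1G17960, AT5G53230, AT5G25230 and DTX1 had log2 ratios of 5.38, 4.96, 4.42, 3.87 and 3.79. Abscisic acid genes had a median of 0.60 (percentile 100), with HAI2 5.01-fold (3.46 to 7.45) and RD29B 3.33-fold (2.98 to 3.74) higher. Osmoprotectant genes had a median of 0.73 (percentile 100), with all 9 above 0 and the proline synthesis gene P5CS1 2.33-fold higher (2.27 to 2.38). Defence genes had a median of 0.32 (percentile 98.9), with PAD3 10.2-fold (8.31 to 12.6) and SARD1 2.96-fold (2.51 to 3.5) higher. Cold-regulated genes had a median of 0.33 (percentile 100), with KIN1 2.23-fold (2.19 to 2.27) and LTI30 2.09-fold (2.05 to 2.13) higher and the other 17 within 2-fold. Flavonoid genes had a median of 0.24 (percentile 99.1), with 10 of 14 above 0. Plastid-encoded genes went both ways, with 10 of 64 at least 2-fold higher and 7 lower (log2 ratios from -1.95 to 2.54) around a median of 0.20 (percentile 100).

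SME1 was also the most reduced gene in the library labelled sme1-1 4 °C. AT1G11740, AT1G15825, AT3G55646, CRK30, AT1G23050, AT4G15660, AT1G15830, AT2G46190 and PHI-1 followed, with log2 ratios from -3.39 to -2.58. FLC was 6.10-fold lower (4.12 to 9.31), while MAF5, another member of the FLC family, was 3.15-fold higher (2.70 to 3.69). The clock gene GI was 3.76-fold higher (3.4 to 4.17) and the splicing regulator SR30 2.33-fold (2.09 to 2.61). Medians inside the middle 95% were 0.13 for LSM genes, 0.01 for splicing regulators, 0.07 for cold signalling, -0.14 for heat shock, 0.03 for photosynthesis, 0.20 for the clock, 0.25 for flowering time, 0.10 for jasmonate, 0.09 for antioxidant enzymes, 0.02 for membrane lipids, -0.21 for the cell cycle, -0.07 for cytosolic ribosomal proteins and -0.30 for mitochondrion-encoded genes. Over all genes, 502 were at least 2-fold higher and 468 at least 2-fold lower in the library labelled sme1-1 4 °C, 5.6% of the genes compared. Library totals gave 543 and 426, and no filter 1349 and 1591.

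Both comparisons of temperature labels shared 77 genes at least 2-fold higher, against 4.5 for independent lists, and 43 at least 2-fold lower, against 3.3. Another 14 genes were at least 2-fold apart in opposite directions. Across genes, Pearson's r was 0.45 and Spearman's rho 0.36. In the additive model 121 genes were higher and 103 lower with the label 4 °C (edgeR, adjusted p below 0.05). SME1 was lower by a log2 fold of -4.69 ± 0.24 (adjusted p = 6.45e-07 in edgeR), FLC by -3.05 ± 0.38 (adjusted p = 0.00188) and AGL24 by -1.86 ± 0.22 (adjusted p = 0.00143). AT3G01345 was higher by 10.33 ± 0.25 (adjusted p = 2.21e-10 in edgeR), NDB4 by 4.59 ± 0.30 and QQS by 3.87 ± 0.35. Of the 19 cold-regulated genes KIN1 alone passed the threshold (1.12 ± 0.19, adjusted p = 0.0122 in edgeR), and adjusted over the list alone 4 were higher and 2 lower. HAI2 and RD29B of the abscisic acid list, SOC1 and MAF5 of the flowering list, P5CS1, HSP70 and FSD1 were higher past the threshold, and CSD1 and CSD2 were lower. HSP70, at an adjusted p of 0.0491 in edgeR, had one of 0.0520 in DESeq2. No LSM gene, splicing regulator, photosynthesis, clock, flavonoid, defence or jasmonate gene passed it in edgeR. Adjusted over each list alone, 6 flavonoid genes, 2 splicing regulators and 2 clock genes were higher and none of the other 4 lists had a call. Of the 64 plastid-encoded genes 6 were higher and 2 lower (14 and 5 adjusted over the list alone). None of the 11 Sm genes, by gene code alone, passed. Their medians were 0.07 in Col-0 and -0.12 in sme1-1 (percentiles 86.3 and 22.5), and -0.17 for the difference (percentile 11.4). The count of 224 genes for this term was 425 with DESeq2's size factors (196 higher, 229 lower) and 353 with library totals (158 higher, 195 lower).

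**Figure D3:**
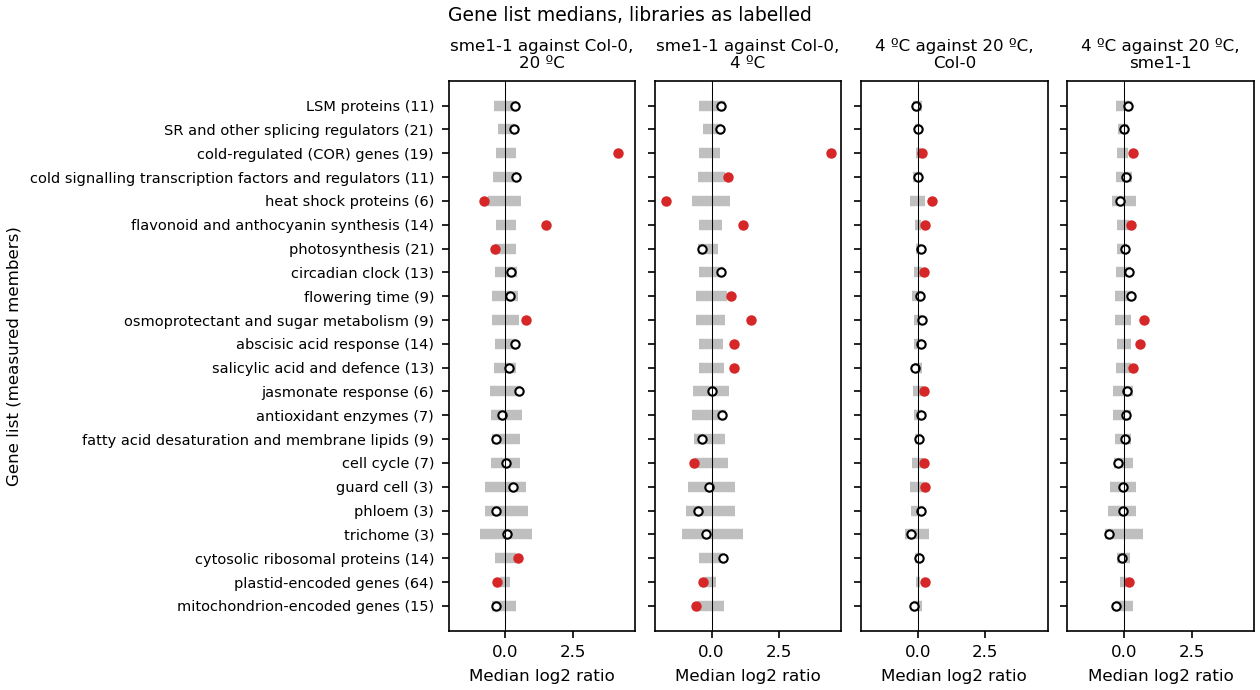
Median log2 ratio of each list fixed before the data were examined (points; measured members in brackets) in the 4 comparisons of libraries as labelled, with the middle 95% of 10000 matched random lists (grey bars); red points lie outside the bar. The cold-regulated list lies at 4.15 and 4.41 between genotype labels and at 0.16 and 0.33 between temperature labels.

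The 2 temperature ratios were then set against each other, sme1-1 minus Col-0 as labelled. Of the 13 defence genes 12 lay above 0: 5 of 13 had a difference of at least 1 on the log2 scale, none of -1 or less, and the median was 0.64 (percentile 100). PAD3 was at 0.635, 2.24 and 0.264 CPM in the first 3 libraries and at 22.8 CPM in that labelled sme1-1 4 °C, a difference of 4.47 ± 0.49 (counting SE). SARD1, PR5 and CBP60G had differences of 1.47, 1.27 and 1.13. CYP71A13, which like PAD3 acts in camalexin synthesis, had a difference of 3.57 ± 0.15, and the glycosyltransferase gene UGT74E2 one of 4.57 ± 0.24. AT2G04050 had the highest, 8.17 ± 0.76, and LEA7, AT4G03450, AT2G18193, AACT1, AT1G26380 and CRK5 lay between 3.79 and 3.07.

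Osmoprotectant genes (median difference 0.68, percentile 100) and abscisic acid genes (0.32, percentile 99.5) also had medians above 0, with SUS1 at 1.16 and NCED3, which makes an abscisic acid precursor, at 0.94. Antioxidant enzymes had a median of 0.29 (percentile 99.4). Heat shock genes lay below 0 (median -0.77, percentile 0, all 6 below 0), with ROF2 at -1.12. Flavonoid genes (-0.29, percentile 1.3), cell cycle genes (-0.39, percentile 1.7) and mitochondrion-encoded genes (-0.38, percentile 0.7) had medians below 0 too, with 3 of 14, 1 of 7 and 5 of 15 members above 0. MIOX2 had the lowest difference, -4.18 ± 0.82, followed by AT1G11740 (-3.77) and AT4G15660 (-2.96). AT1G15825, AT2G30540, CRK30, AT1G04770, FTM1, MYB5 and AT3G49950 lay between -2.60 and -2.17. Cold-regulated genes had a median of 0.09 (percentile 96.7), with LTI30 at 2.07, COR27 at 1.23 and GRP7, a cold-induced RNA-binding protein, at -0.96. Medians inside the middle 95% were also -0.03 for LSM genes, -0.01 for splicing regulators, -0.02 for cold signalling, -0.10 for photosynthesis, -0.14 for the clock, 0.29 for flowering time, -0.35 for jasmonate, 0.01 for membrane lipids, -0.16 for cytosolic ribosomal proteins and -0.03 for plastid-encoded genes. With library totals in place of TMM, the medians of LSM genes, splicing regulators, cold signalling and plastid-encoded genes changed sign, to 0.04, 0.05, 0.05 and 0.03. Over all genes, 444 had a difference of at least 1 and 352 of -1 or less, 4.6% of the genes compared, with 55.8% of them above 0. With library totals the split was 547 and 273, with 66.7% above 0, and without a filter 1705 and 1737. The interaction could not be tested, since a model that holds it has no residual degrees of freedom with 4 libraries.

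Markers of other cell types and organs were followed in the same libraries. Guard cell markers (3 genes) had medians of 0.29 and -0.11 between genotype labels at 20 °C and 4 °C, and of 0.28 and -0.04 between temperature labels in Col-0 and sme1-1. Phloem markers (3 genes) had medians of -0.36, -0.50, 0.10 and -0.03 in the same order, and trichome markers (3 genes) 0.06, -0.22, -0.27 and -0.57. In the difference between the 2 temperature ratios the 3 lists were at -0.36, -0.01 and -0.28, and the phloem median was 0.05 with library totals. Of the meristem and root markers 2 each passed the filter: STM and KNAT1 lay between 2.52 and 11.4 CPM, SHR between 12.5 and 16.5 CPM, and SCR at 128 and 125 CPM in the libraries labelled Col-0 and at 63.6 and 55.3 CPM in those labelled sme1-1. None of the 3 seed storage genes passed it.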

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

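In this part, the tests of exchanged labels, of a single wrong label and of other cell types were chosen only after the result was seen, as were the second cold list, the mitochondrial dysfunction list and the DNA damage list.

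Some genes were at least 2-fold apart in opposite directions in 2 comparisons of the same contrast and drew attention for that reason; these differences were not tested. Between the libraries labelled sme1-1 and Col-0, the log2 ratio at 4 °C and at 20 °C was 2.95 and -5.21 for AT2G04050, 2.90 and -1.67 for UGT74E2, 1.89 and -1.83 for AT2G18193, 1.2 and -2.37 for CYP71A13, 1.14 and -1.51 for AT1G17960, and 1.03 and -1.19 for OM66. Between the libraries labelled 4 °C and 20 °C, the log2 ratio in sme1-1 and in Col-0 was 6.66 and -1.50 for AT2G04050, 3.32 and -1.14 for PAD3, 2.75 and -1.04 for LEA7, 2.53 and -1.04 for CYP71A13, 2.34 and -1.43 for AT4G03450, 2.11 and -1.04 for AACT1, 2.06 and -1.04 for AT1G26380, and 1.06 and -1.01 for LTI30.

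SME1 divided the 4 libraries by temperature label, and cold-regulated genes divided them by genotype label. Of the 24 ways to place the 4 labels, 1 leaves SME1 at least 2-fold lower in sme1-1 at both temperatures and the cold-regulated median at least 2-fold higher at 4 °C in both genotypes: an exchange of the labels sme1-1 20 °C and Col-0 4 °C, a count that restates the observation that prompted it and is no independent support. A single wrong label, with 2 libraries allowed under 1 label, does not bring both in line, which follows from these same values and is no separate evidence: of 12 changes of 1 label, 0 leave SME1 at least 2-fold lower in every sme1-1 library than in every Col-0 library and the cold-regulated median at least 2-fold higher in every 4 °C library than in every 20 °C library. A cold list unsuited to these plants is argued against by a second cold list. Its median was 0.21 (percentile 99.8) in the library labelled Col-0 4 °C against that labelled Col-0 20 °C. The second list was also chosen after the result was seen in these libraries, so it is not independent of that result. If the labels are right, sme1-1 plants carry high levels of cold-regulated genes while SME1 falls in the cold. Cold-regulated genes would then scarcely differ after 24 h at 4 °C in either genotype. Their medians between temperature labels were 0.16 in Col-0 and 0.33 in sme1-1, with 16 and 17 of 19 within 2-fold. Between genotype labels they were 4.15 and 4.41. For cold-regulated genes, these values argue against the labels as given. An exchange was not checked by other means. Under an exchange, the comparisons of genotype and of temperature would trade names, and the difference between the temperature ratios would stay the same.

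Genes at least 2-fold apart the same way in both comparisons of temperature labels included SME1, AT3G01345 and FLC. They would belong to temperature under the labels as given and to the mutant line under exchanged labels, which was not tested with these genes. Differences carried along with the SME1 locus were tested by position: 4 of 119 genes lay within 2 Mb of it, against 3.8 expected, a ratio of 1.07, which does not support linkage. The choice among TMM, DESeq2's size factors and library totals does not account for them either. At least 95% of the 120 genes stayed at least 2-fold apart in both comparisons under the other scalings. These scalings differ little, with TMM factors from 0.964 to 1.036, so a larger scaling error was not tested. A DNA damage response remains open, with the list median at percentile 79.4 in the lower of the 2 comparisons.

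Defence genes as a list (median difference 0.64), and UGT74E2 and AT2G04050 as single genes, were higher in the library labelled sme1-1 4 °C than the other 3 libraries add up to. A mitochondrial dysfunction response in this library could account for part of this, but remains untested. That list's median difference lay at percentile 100 of its random lists, and also did without OM66 (4 genes, median difference 1.92). The list was chosen after this pattern was seen in the same libraries, so the percentile is no independent support. More of another cell type in the leaf material is not supported, with a highest marker median of -0.01. A deviation of this 1 library that is not due to genotype or temperature cannot be excluded, since there is 1 library per group.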

How the results depend on the processing

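No alternative turned the direction of a called result for a gene or list. The balance of higher and lower genes did turn. For the temperature term it was 121 and 103, but 158 and 195 with library totals and 96 and 123 with a mean of at least 5 CPM. DESeq2 in place of edgeR kept it, with 110 and 106. Of the summary values recomputed under the alternatives, 72 stayed within their limits and 22 moved; among single genes and lists, 7697 stayed, 108 moved, 61 newly passed the threshold and 42 no longer passed it. The counts of genes at least 2-fold apart (sme1-1 against Col-0 at 20 °C and 4 °C, 4 °C against 20 °C in Col-0 and sme1-1, and the difference between these) were 5108, 5686, 2247, 2940 and 3442 without a filter, where more genes with few reads are compared, and 924, 1205, 65, 239 and 180 at 3-fold. With a mean of at least 5 CPM, where fewer genes are compared, the first and the last 3 were 1831, 80, 468 and 317. Without a filter, 5 lists lay outside the middle 95% for the difference between the temperature ratios, in place of 8. Pearson's r between the genotype ratios was 0.68 without a filter and 0.88 with at least 5 CPM, and that between the temperature ratios 0.31 without a filter. The temperature term's count was 460 at an adjusted p of 0.1, 475 without a filter, 425 with DESeq2's size factors and 353 with library totals (edgeR); the cause of the last 2 was not tested. No paired analysis was possible because each group has 1 library. Leaving out 1 library leaves the additive model no residual degrees of freedom. Without the 2 libraries whose labels are in doubt, the library labelled sme1-1 4 °C against that labelled Col-0 20 °C (chosen after seeing the data) had 1848 genes higher and 1884 lower. With every list member used by its gene code, also chosen after seeing the data, 9, 13, 8, 6 and 8 lists lay outside the middle 95%, against 7, 11, 8, 6 and 8. The Sm and LSM list by gene code had medians of 0.41 and 0.38 (percentiles 99.7 and 98.6) between genotype labels, in place of 0.35 and 0.36 for its LSM members.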

Other observations

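The lists in this part were chosen after the data were seen. Their percentiles and their counts adjusted over the list alone are therefore no independent support. Phosphate starvation genes were lower in the libraries labelled sme1-1: the median log2 ratio was -1.36 (percentile 0) at 20 °C and -1.19 (percentile 0.1) at 4 °C, with 5 of 6 at least 2-fold lower in each. SPX1, a phosphate sensor, was 7.34-fold (5.90 to 9.23) and 7.71-fold (6.22 to 9.65) lower, and SQD1, which makes sulfolipids that replace phospholipids, 2.51-fold (2.39 to 2.65) and 2.47-fold (2.35 to 2.60). In the additive model all 6 fell with the label sme1-1 (edgeR, adjusted p below 0.05), and also when adjusted over the list alone; in DESeq2, PHT1;4 (adjusted p = 0.0641) and PLDZETA2 (0.158) did not pass, which left 4 of 6. Between temperature labels the medians were -0.05 in Col-0 and -0.02 in sme1-1. Iron deficiency genes had medians of -1.03 (percentile 0.4) and -0.62 (percentile 6.6) between genotype labels and -0.37 (percentile 0.1) and -0.18 (percentile 24.7) between temperature labels, with the iron reductase gene FRO3 5.61-fold (4.65 to 6.81) and 4.73-fold (3.85 to 5.86) lower in the libraries labelled sme1-1. A second cold list, with the early light-induced gene ELIP2 (7.14-fold, 6.72 to 7.60, and 6.19-fold, 5.91 to 6.49, higher) and the starch-degrading kinase gene SEX1 (4.85-fold, 4.66 to 5.04, and 4.94-fold, 4.78 to 5.11), had medians of 1.65 and 1.72 (percentile 100 in both) between genotype labels and 0.21 and 0.40 (percentile 99.8 in both) between temperature labels.

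Of 9 glucosinolate genes 8 were above 0 in each comparison of temperature labels and none was 2-fold apart, with medians of 0.56 in Col-0 and 0.45 in sme1-1 (percentile 100 in both). CYP79F1, at the entry to aliphatic glucosinolates, was 1.64-fold (1.60 to 1.69) and 1.61-fold (1.57 to 1.64) higher, and BCAT4 1.54-fold (1.47 to 1.61) and 1.56-fold (1.51 to 1.61). In the additive model none passed the threshold (edgeR). When adjusted over the list alone 6 did, but this list was chosen after the data were seen. Between genotype labels the medians were 0.21 and 0.20 (percentiles 75.9 and 82.2). Of the DNA damage list, GMI1, a gene of double-strand break repair, was 4.48-fold (3.71 to 5.45) and 8.37-fold (6.83 to 10.3) higher in the libraries labelled 4 °C, and rose in the additive model by 2.61 (adjusted p = 1.72e-04 in edgeR); the list's medians were 0.48 (percentile 100) and 0.16. All 5 measured mitochondrial dysfunction genes were at least 2-fold higher in the library labelled sme1-1 4 °C than in either neighbour, with medians of 1.72 against Col-0 4 °C and 1.60 against sme1-1 20 °C (percentile 100 in both). The alternative oxidase gene AOX1A was 3.30-fold (3.05 to 3.56) and 3.03-fold (2.81 to 3.26) higher. In the other comparisons this list's medians were -0.30 between the libraries labelled 20 °C and -0.21 between those labelled Col-0.

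Plastid-encoded genes held 1.51% and 1.72% of the counts in the libraries labelled Col-0 20 °C and 4 °C, and 1.1% and 1.31% in those labelled sme1-1. Mitochondrion-encoded genes held 0.0430%, 0.0400%, 0.0400% and 0.0230% in the libraries labelled Col-0 20 °C, sme1-1 20 °C, Col-0 4 °C and sme1-1 4 °C. Whether library preparation accounts for the lower share in the library labelled sme1-1 4 °C was not tested.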
